A study of Mus musculus with 4 samples.

How the data were processed

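RNA immunoprecipitation and sequencing (RIP-seq) was carried out on AML12 cells, a non-tumour mouse hepatocyte line. Per the labels' protocols, cells grown with 10% serum and 0.1 µM dexamethasone were crosslinked with ultraviolet light and their nuclei were lysed and sonicated. Each lysate was then divided between an antibody against SAFB and control IgG, after a small input had been set aside. The input was not analysed here. RNA from the precipitates was treated with DNase, depleted of ribosomal RNA and made into strand-specific Illumina libraries. The labels place 2 libraries in the IgG group and 2 in the SAFB group. They number the libraries 1 and 2 within each group, do not say that replicates came from separate cultures, and do not say that equal numbers mark a shared lysate. The p-values of single genes therefore measure only the spread between these libraries.

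The authors deposited 1 table of TPM values, transcript shares scaled to 1000000 per library. The submitters' processing notes name HISAT2, HTSeq, DESeq2, StringTie and the genome build mm10, without versions or roles. The tool behind the TPM values, the annotation release and the use of strand in counting are not given in the sources used here. TPM values keep no read depth, so the depth of each library is unknown and no counting interval is given. An entry of 0 is described only as listed at 0. Because TPM is a share of each library, an RNA that takes up much of a library lowers the values of all others. Without knowledge of strand use, values of antisense and overlapping genes are uncertain, as are those of processed pseudogenes and multicopy RNAs that share sequence.

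The table held 52197 entries with 52189 distinct Ensembl identifiers. Entries that shared an identifier (14 entries, 6 identifiers) were summed. Of the identifiers, 52042 were found in GENCODE release M21, whose assembly is the one called mm10, and coordinates, biotypes and transcript sequences were taken from it. The remaining 147 have no coordinates here. In the table, 27 symbols read as calendar dates and were kept as they stand. No per-sample column was left unmatched. In all, 28294 genes were listed at 0 in every library.

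Genes with at least 1 TPM in at least 2 of the 4 libraries were tested, which left 16647. A gene can thus enter through the 2 libraries of 1 group alone. Values were taken as log2(TPM + 1), so fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 fitted the 2 groups, with moderated variances that follow a trend with mean level, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 2.50. Errors of fold changes are standard errors, and errors of TPM means are SD over 2 libraries. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so none was used for single values.

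Before the data were examined, 23 gene lists were fixed, of which 21 had at least 3 members tested. The lists of ribosomal RNA and of repeats matched 0 entries. Lists were compared with the other genes by limma's camera, two-sided, with a preset correlation of 0.01, and again with an estimated correlation. With the preset correlation the degrees of freedom come from the number of genes, which are not independent replicates. Small p-values there do not measure the spread between libraries alone. With an estimated correlation the test rests on only 2 residual degrees of freedom. A list that did not pass there was therefore not shown to lack a shift. A further test, fry, asks only whether a list's genes move one way on balance. The rule for named genes was also fixed then. It takes, in each direction, the 15 genes with the largest fold change among those past the threshold whose groups do not overlap and whose higher group reaches a mean of 5 TPM, and the 5 such genes with the highest mean TPM. It adds Safb, Safb2 and Sltm, and up to 4 members of each list with the highest mean TPM. Predicted symbols (Gm with digits, or ending in Rik) enter at most 3 per direction, and the text may summarise those after the first 10.

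The procedure was tested on simulated libraries of 16647 genes with the means of the real genes and spreads drawn from the fitted variance prior. With 200 genes changed, 0% of those changed 2-fold and 0% of those changed 4-fold were recovered, and 0 unchanged genes were called. With 4000 genes changed, all upward, 40.0% of 2-fold and 79.3% of 4-fold genes were recovered, and 3.95% of calls were unchanged genes. The simulation gave both groups the same spread and drew genes independently. In the data the median absolute log2 difference between the IgG libraries was 2.23 times that between the SAFB libraries. The 3.95% therefore does not carry over to the real calls. The simulated list with a shift was called and 0 lists without one were.

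In all, 18 alternatives were run. They cover the pseudocount, the filter, the scaling between libraries (median centring, quantile normalization, leaving out mitochondrial and small structured RNAs), the variance model, a replicate block and leaving out each library. Besides these, the calls were counted again with an absolute log2 fold change of at least 1 required. Of these, 4 were added after the data had been seen: rescaling of protein-coding genes alone, removal of a transcript length trend, removal of a GC trend (lowess span 0.3) and keeping entries with a shared identifier separate. Sequence features of 11896 protein-coding genes were taken from the longest transcript of at least 500 bp, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Their rank correlations have 95% bootstrap intervals over 200 draws of genes. Figures were drawn with matplotlib 3.10.9.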

Results

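RIP-seq measured which nuclear RNAs of AML12 mouse hepatocytes were recovered with an antibody against SAFB (scaffold attachment factor B), a nuclear matrix protein that binds RNA and DNA. Control IgG served as background. The series was designed to identify RNAs associated with SAFB, and its single comparison is the SAFB RIP (2 libraries) against the IgG RIP (2 libraries). Values are TPM and the read depth is unknown. Positions are on mm10 with the GENCODE release M21 annotation. The IgG libraries held 16036 and 17284 entries above 0, and the SAFB libraries 22395 and 21012. In log2(TPM + 1), the IgG libraries correlated with each other at r = 0.923 across genes, the SAFB libraries at 0.979, and pairs of 1 library from each group at 0.830 to 0.862.

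The 3 genes of the SAFB family were all higher in the SAFB RIP. Safb2, which encodes the paralog of SAFB, rose from 230.5 ± 5.95 to 1837 ± 73.2 TPM (SD, n = 2), a log2 fold change of 2.99 ± 0.10 (SE). Safb rose from 166 ± 5.99 to 934 ± 76.3 TPM, by 2.49 ± 0.11. Sltm, the SAFB-like transcription modulator gene, rose from 55.2 ± 11.2 to 151 ± 1.10 TPM, by 1.44 ± 0.17. Many zinc finger protein genes were higher too, while the 7SL copies Rn7s1 and Rn7s2, the RNAs of RNase P and RNase MRP and 11 of 31 mitochondrially encoded genes were lower.

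Of 16647 genes tested, 6346 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 4964 higher and 1382 lower in the SAFB RIP. The median log2 fold change of all genes tested was 0.46, so changes are also given relative to it, after centring each library on its median. That scaling left 2736 genes higher and 2935 lower. All 2736 were among the 4964, and all 1382 stayed lower. Quantile normalization gave 2758 higher and 2986 lower. Rescaling protein-coding genes alone, an alternative added after the data had been seen, gave 2600 higher and 2322 lower. Removing a GC trend, also added then, gave 4033 higher and 928 lower, which kept 3547 of the 4964 and only 611 of the 1382. Leaving out 1 library moved the counts too. In all, 2605 genes passed without SAFB RIP replicate 1, 3080 without SAFB RIP replicate 2 and 10412 without IgG RIP replicate 2, and without IgG RIP replicate 1 2325 were lower. In 8714 genes both SAFB libraries lay above both IgG libraries and in 3558 below, together 73.7% of those tested. For a single gene chance gives 33.3%, but all genes share the same 4 libraries. A shift between the groups, such as the median of 0.46, can separate many genes at once, so the 2 percentages do not measure evidence gene by gene. Among the genes called higher, 711 were listed at 0 in both IgG libraries, and among those called lower 11 were listed at 0 in both SAFB libraries.

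The groups differed in composition. AY036118, Gm26917 and Gm42418, annotated noncoding RNAs at or beside a ribosomal DNA fragment on chromosome 17, took 16.8% ± 2.76 (SD, n = 2) of the TPM in the IgG RIP and 1.26% ± 0.369 in the SAFB RIP. AY036118 (chromosome 17, 39847113 to 39848035) overlaps Gm42418 on the other strand, and both overlap Rn18s-rs5, so their values are uncertain. Protein-coding genes took 67.9% ± 0.121 of TPM in the IgG RIP and 83.7% ± 0.0358 in the SAFB RIP. The 10 most abundant entries held 27.5% and 26.8% of the IgG libraries, against 9.59% and 9.73% of the SAFB libraries. With 2 libraries per group, the smallest exact permutation p is 0.333, so these shares are given as values.

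**Figure D1:**
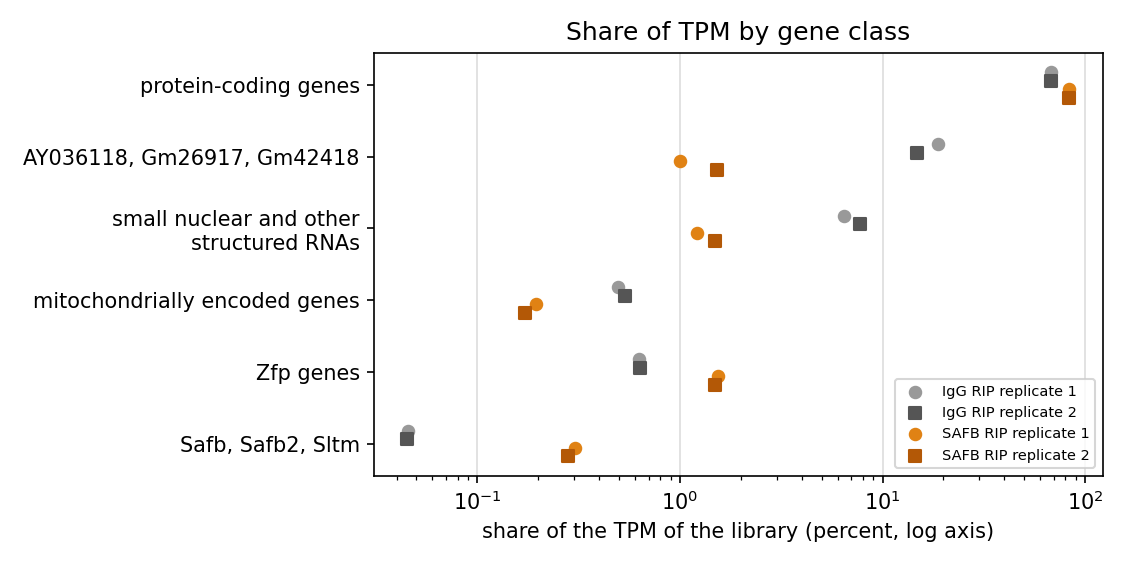
Share of the TPM of each library (percent, log axis) taken by 6 gene classes, with 1 point per library. The classes Safb, Safb2, Sltm and Zfp genes lie higher in both SAFB libraries, and AY036118, Gm26917 and Gm42418 lie at 1.001% and 1.52% there against 18.7% and 14.8% in the IgG libraries.

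Safb (chromosome 17, 56584825 to 56606294, plus strand) and Safb2 (56560965 to 56584585, minus strand) are neighbours on opposite strands. All 3 family genes passed among all genes and when adjusted over the list alone, and all 3 passed after median centring, at 2.03 for Safb, 2.53 for Safb2 and 0.98 for Sltm. The list stood above other genes (limma camera, Benjamini-Hochberg adjusted p = 0.0141), but not with an estimated correlation (adjusted p = 0.381 with an estimated correlation).

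Among the most abundant genes that were higher, Cp, which encodes ceruloplasmin, a copper-carrying plasma protein, rose from 1529.5 ± 30.1 to 4988 ± 294 TPM (1.70 ± 0.13). It stood at 1.24 after median centring, 1.40 with protein-coding genes alone and 2.88 after quantile normalization, which moves genes by rank. Ahnak, a gene for a very large scaffold protein (chromosome 19, 8989284 to 9076914), rose from 1111 ± 106 to 4107 ± 55.1 TPM (1.89 ± 0.13). Peg3, a paternally expressed imprinted gene for a zinc finger protein (chromosome 7, 6703892 to 6730431), rose from 703 ± 10.96 to 4074 ± 283 TPM (2.53 ± 0.12). Tpt1 (translationally controlled tumour protein) at 1.05 ± 0.16 and Gsta3 (a glutathione transferase) at 0.48 ± 0.12 passed as deposited, but not after median centring, where they stood at 0.59 and 0.02. Gm27597, at 0.69, lies in an exon of Rpl19 and Gm15772, at 0.94, is a processed pseudogene. Neither passed after median centring, at 0.23 and 0.48.

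**Figure D2:**
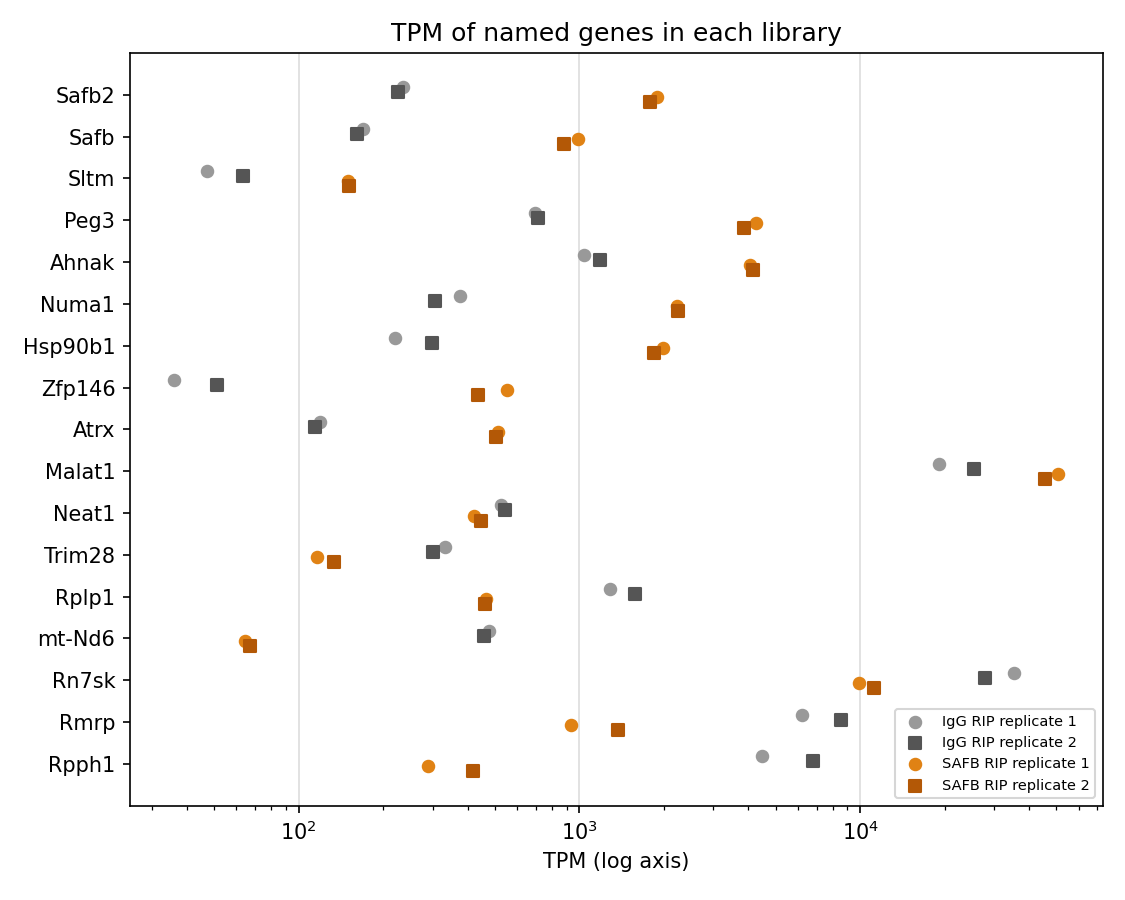
TPM (log axis) of 17 named genes, with 1 point for each of the 2 IgG and 2 SAFB libraries. Safb2 and Safb lie higher in both SAFB libraries, while mt-Nd6, Rmrp and Rpph1 lie lower in both. Rn7sk, lower here, stood on the log2 scale at -2.03 after median centring and at 0.63 after quantile normalization, which moves genes by rank.

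Zinc finger protein (Zfp) genes, most of which encode DNA-binding transcription factors, formed the largest list. Of 340 tested, 191 rose, 1 fell and 148 did not pass, and 211 rose and 4 fell when adjusted over the list alone. Their median log2 fold change was 1.37, or 0.91 after median centring, where 130 rose and 12 fell. Zfp146 (chromosome 7, 30161269 to 30169750) rose from 43.6 ± 10.7 to 494 ± 83.3 TPM, by 3.48 ± 0.22. Zfp512 rose by 1.62 ± 0.09 and Zfp445, a regulator of imprinted loci, by 1.42 ± 0.14, while Zfp207, at 0.61, no longer passed after median centring, at 0.15. The list stood above other genes (limma camera, Benjamini-Hochberg adjusted p = 7.22e-08), but not with an estimated correlation (adjusted p = 0.381 with an estimated correlation). In limma fry, which does not compare a list with other genes, its Benjamini-Hochberg adjusted p was 0.00633. Very long genes had the same value in fry, and heterochromatin factor genes, which did not stand apart in camera, had 0.00254. Histone genes and small nucleolar and Cajal body RNAs did not pass in fry, at 0.0918 and 0.104. With a median of 0.46 over all genes, an upward result in fry does not set a list apart.

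Of 42 very long genes tested, 19 rose and 0 fell in limma, 21 and 0 when adjusted over the list alone, and 7 rose and 4 fell after median centring. Ank3, the ankyrin G gene, stood at 0.69 ± 0.10 and Dock1, a guanine nucleotide exchange factor gene, at 0.57 ± 0.12. Exoc4, of the exocyst complex, did not pass at 0.19 ± 0.10, and stood at -0.27 after median centring. Neither Ank3 nor Dock1 passed after median centring, at 0.23 and 0.11. The list passed as deposited (limma camera, Benjamini-Hochberg adjusted p = 0.0141), but not with an estimated correlation (adjusted p = 0.381 with an estimated correlation) and not after median centring (adjusted p = 0.198). Nor did it pass after quantile normalization, with mitochondrial and small structured RNAs left out or with protein-coding genes alone. It also did not pass with a transcript length trend or a GC trend removed.

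Genes for nuclear matrix and hnRNP proteins did not stand apart from other genes as a list (limma camera, Benjamini-Hochberg adjusted p = 0.0798). Of 33 tested, 16 rose and 1 fell, and 17 rose and 1 fell when adjusted over the list alone, against 9 and 5 after median centring. Numa1, which encodes a nuclear matrix and spindle pole protein (chromosome 7, 101934111 to 102014964), rose from 341 ± 49.6 to 2242 ± 14.2 TPM, by 2.72 ± 0.14. Hnrnpf rose by 1.86 ± 0.16 and Hnrnpab by 1.29 ± 0.11, and Hnrnpa2b1 did not pass at 0.56 ± 0.16. Of 24 genes for SR and SR-like splicing factors, 12 rose and 1 fell, with the same counts when adjusted over the list alone, against 5 and 3 after median centring. Son, which encodes a scaffold protein of nuclear speckles, rose by 1.52 ± 0.12. Srsf2 stood at -0.10 ± 0.09 and did not pass as deposited, but passed as lower after median centring, at -0.56. The list did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.102).

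Of 38 heterochromatin factor genes, 16 rose and 2 fell, or 16 and 4 when adjusted over the list alone, and 12 and 6 after median centring. Atrx, which encodes a chromatin remodeller (chromosome X, 105797615 to 105929403), rose from 117 ± 3.84 to 510.4 ± 5.36 TPM, by 2.12 ± 0.09. Mbd1, a gene for a methyl-CpG binding protein, rose by 1.71 ± 0.11. Chd4 rose by 0.70 ± 0.10 as deposited and did not pass after median centring, at 0.24. Trim28, which encodes the KAP1 corepressor, fell from 317 ± 22.7 to 125 ± 12.5 TPM (-1.34 ± 0.12). Of 29 Polycomb and Trithorax genes, 8 rose and 3 fell, or 10 and 3 when adjusted over the list alone, and 8 and 5 after median centring, among them Asxl1 (1.78 ± 0.10), Bptf (1.66 ± 0.17) and Ezh2 (1.27 ± 0.17), which all rose. Neither list stood apart from other genes (limma camera, Benjamini-Hochberg adjusted p = 0.347 and 0.832).

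Of 23 heat shock and chaperone genes, 12 rose and 2 fell, or 12 and 3 when adjusted over the list alone, 10 and 6 after median centring, and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.347). Hsp90b1, which encodes the endoplasmic reticulum chaperone GRP94 (chromosome 10, 86690209 to 86705509), rose from 259.8 ± 54.7 to 1920 ± 96.3 TPM, by 2.90 ± 0.17. Hspa8 rose by 1.08 ± 0.10. Hsp90ab1, at 0.96 ± 0.12, and Hspa5, at 0.93 ± 0.23, passed as deposited and not after median centring, at 0.50 and 0.47.

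Several abundant structured RNAs were lower in the SAFB RIP. Of 17 tested in the list of small nuclear and other structured RNAs, 11 fell and 1 rose, or 12 and 1 when adjusted over the list alone, with a median of -2.28. Rpph1, the RNA of RNase P (chromosome 14, 50807449 to 50807767), fell from 5636 ± 1641 to 353 ± 91.1 TPM (-3.99 ± 0.29). Rmrp, the RNA of RNase MRP, fell from 7378 ± 1657 to 1151 ± 311 TPM (-2.69 ± 0.27). Rpph1 overlaps an exon of Ccnb1ip1 on the same strand and Rmrp an exon of Ccdc107 on the opposite strand, so their values carry some uncertainty. Rn7s1 and Rn7s2, near-identical copies of the 7SL RNA of the signal recognition particle, stood at -4.32 ± 0.39 and -4.21 ± 0.47 and are uncertain as single genes. Rprl3 (-3.76) and Rnu3b2, a copy of U3 (-3.09), fell as well, as did the U3 copies Rnu3b1 (-2.28), Rnu3b3 (-2.76) and Rnu3b4 (-2.70). Copies of U3 and of 7SL count as separate genes in the list, so its median and its test weigh these RNAs more than once. The gene that rose was Rnu6, the U6 small nuclear RNA, at 2.45. The small nuclear RNA genes Rnu1a1 (0.46), Rnu12 (0.999) and Rnu2-10 (-1.15) did not pass. The median of -2.28 therefore does not describe the small nuclear RNAs of the list. Rn7sk, the 7SK RNA, fell from 31529 ± 5256 to 10530 ± 910 TPM (-1.57 ± 0.29), and stood at -2.03 after median centring. After quantile normalization it stood at 0.63. That method moves genes by rank, and AY036118 and Gm26917 lay above Rn7sk in both IgG libraries and below it in both SAFB libraries. The direction of Rn7sk thus depends on whether ranks or TPM are compared. The annotated class of small nuclear RNAs, a group added after the data had been seen, did not share these falls, with 47 of 156 higher and 2 lower and a median of 1.02. The list stood below other genes (limma camera, Benjamini-Hochberg adjusted p = 7.22e-08; adjusted p = 0.381 with an estimated correlation).

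Of 31 mitochondrially encoded genes tested, 11 fell and 0 rose, with the same counts when adjusted over the list alone and 16 and 0 after median centring, and the median was -1.25. They took 0.514% ± 0.0262 of the TPM in the IgG RIP and 0.182% ± 0.0161 in the SAFB RIP. mt-Nd6, the only protein-coding gene here on the light strand (mitochondrial genome, 13552 to 14070), fell from 467 ± 13.8 to 65.8 ± 1.98 TPM (-2.81 ± 0.09). mt-Nd5, whose end it overlaps on the opposite strand, stood at -2.02 ± 0.09, mt-Cytb at -1.73 ± 0.09 and mt-Co1 at -1.18 ± 0.15, all lower. The list stood below other genes (limma camera, Benjamini-Hochberg adjusted p = 1.10e-11; adjusted p = 0.303 with an estimated correlation).

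Of 97 small nucleolar and Cajal body RNAs, 17 fell and 6 rose, or 11 and 3 when adjusted over the list alone and 25 and 2 after median centring, with a median of -0.31. The wider annotated class of snoRNAs, a group added after the data had been seen, held 40 higher and 26 lower of 271, with a median of 0.06. That class still stood below other genes (limma camera, Benjamini-Hochberg adjusted p = 0.00225; adjusted p = 0.319 with an estimated correlation). The class of scaRNAs, also added then, held 5 higher and 5 lower of 24 and did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.123). Snord14d (-5.34 ± 0.43), Snora75 (-4.32 ± 0.34), Snord88a (-4.02 ± 0.31), Scarna2 (-3.82 ± 0.18) and Snora57 (-1.57 ± 0.20) fell, as did the predicted small RNAs Gm23262 (-5.28 ± 0.33) and Gm22009 (-3.96 ± 0.10). Snord14d lies in the model of Hspa8, Snora75 in that of Ncl, Gm23262 in that of Eif4g2, Snord88a in that of 2410002F23Rik and Gm22009 in an intron of Kpna4. All are on the same strand as these genes, so their values are uncertain. The list stood below other genes (limma camera, Benjamini-Hochberg adjusted p = 5.97e-06; adjusted p = 0.381 with an estimated correlation). Of 14 snoRNA host genes, 0 rose and 2 fell, 0 and 0 when adjusted over the list alone, and 0 rose and 4 fell after median centring. Snhg1 stood at -0.80 ± 0.20, and Gas5 at -0.04 ± 0.15 did not pass. The mean of this list was 0.06, while its test pointed down and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.139).

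Of 67 replication-dependent histone genes, 13 fell and 5 rose, or 13 and 3 when adjusted over the list alone, and 22 and 1 after median centring. The median was -0.13, and 0.23 once a GC trend was removed, an alternative added after the data had been seen. Hist1h1e, a linker histone gene, rose by 1.47 ± 0.31 as deposited and not after median centring, at 1.01, and Hist1h4n, at -0.70 ± 0.20, did not pass as deposited, but passed as lower after median centring, at -1.16, and after quantile normalization, at -1.02. The list stood below other genes (limma camera, Benjamini-Hochberg adjusted p = 1.42e-05; adjusted p = 0.381 with an estimated correlation), and not with the GC trend removed (adjusted p = 0.232). Of 84 cytosolic ribosomal protein genes, 25 rose and 18 fell, or 33 and 22 when adjusted over the list alone. Rplp1, of the ribosomal stalk, fell from 1431 ± 202 to 463 ± 2.16 TPM (-1.62 ± 0.13) and Rps14 stood at -0.87 ± 0.10. Rpl7 rose by 0.58 ± 0.10 as deposited and not after median centring, at 0.12. The median of the ribosomal protein list was 0.21, while its test against other genes pointed down and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.301). After median centring 10 rose and 29 fell, the median was -0.25 and the list passed (adjusted p = 0.0193). As deposited it did not pass with an estimated correlation either (adjusted p = 0.766 with an estimated correlation), and that test was not made after median centring.

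Of 18 nuclear long noncoding RNAs, 5 rose and 1 fell, with the same counts when adjusted over the list alone, 3 and 3 after median centring, and the list did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.810). Malat1, the most abundant of them in the SAFB RIP, stood at 22238 ± 4495 TPM in the IgG RIP and 48292 ± 3582 TPM in the SAFB RIP (1.13 ± 0.37) and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0740). Malat1 did not pass after median centring either, at 0.67 (adjusted p = 0.290), nor with mitochondrial and small structured RNAs left out, at 1.04. It passed as higher after quantile normalization, at 2.85 (adjusted p = 0.00308), so its call depends on the scaling. That method moves genes by rank, and AY036118, Gm26917 and Rn7sk lay above Malat1 in both IgG libraries and below it in both SAFB libraries. Neat1, the paraspeckle RNA, stood at -0.31 ± 0.09 and Firre at 0.27 ± 0.10. Neither passed as deposited. After median centring Neat1 passed as lower, at -0.77, and Firre stood at -0.19. Gm26917 fell, at -3.15 ± 0.30 as deposited and -1.04 after quantile normalization, and Gm42418, outside the list, fell at -3.24 ± 0.17. Gm23833 (chromosome 17, 12770631 to 12770882), a predicted small RNA in an intron of the noncoding RNA Airn on the same strand, rose from 105 ± 21.7 to 2215 ± 66.1 TPM, by 4.40 ± 0.17.

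Marker genes of the cell line and of other cell types were measured as background. Of 20 hepatocyte genes, 5 rose and 3 fell, with the same counts when adjusted over the list alone, and 3 rose and 7 fell after median centring. Those past the threshold as deposited included Apob (1.03 ± 0.13) and the transferrin gene Trf (-0.59 ± 0.14). C3 stood at 0.33 ± 0.16 and Ttr at -0.13 ± 0.12, and neither passed as deposited, though Ttr did after median centring, at -0.59. The hepatocyte median was -0.02 and the mean 0.18, and the test pointed down without passing (limma camera, Benjamini-Hochberg adjusted p = 0.347). Of 7 cholangiocyte and progenitor markers, 1 rose and 2 fell, or 2 and 2 when adjusted over the list alone, and 0 and 3 after median centring. Krt19, at -0.62 ± 0.15, passed as deposited and stood at 0.02 with a GC trend removed. Of 4 fibroblast and stellate markers and 4 macrophage, lymphocyte and endothelial markers, 0 passed as deposited in limma or when adjusted over the list alone, while 2 and 1 fell after median centring. Fn1 stood at 0.18 ± 0.12, Vim at -0.06 ± 0.11 and Cd14 at -0.14 ± 0.14, of which Vim, at -0.52, and Cd14, at -0.60, passed as lower after median centring. Tests of these 3 lists pointed down and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.358, 0.564 and 0.832), while their means were 0.14, -0.10 and 0.47 and their medians 0.00, 0.06 and 0.30. Of 28 cell cycle genes, 9 rose and 0 fell, with the same counts when adjusted over the list alone, and 7 rose and 6 fell after median centring. Those that rose as deposited included Top2a (1.98 ± 0.37) and Pcna (1.09 ± 0.23), of which Pcna did not pass after median centring, at 0.63. That list did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.983). Of 14 immediate early genes, 2 rose and 2 fell, again the same when adjusted over the list alone, against 0 and 4 after median centring, with Klf6 at 0.79 ± 0.16, Dusp1 at -0.68 ± 0.11 and Jund at -0.93 ± 0.14. Klf6 did not pass after median centring, at 0.33, and the list did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.139).

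**Figure D3:**
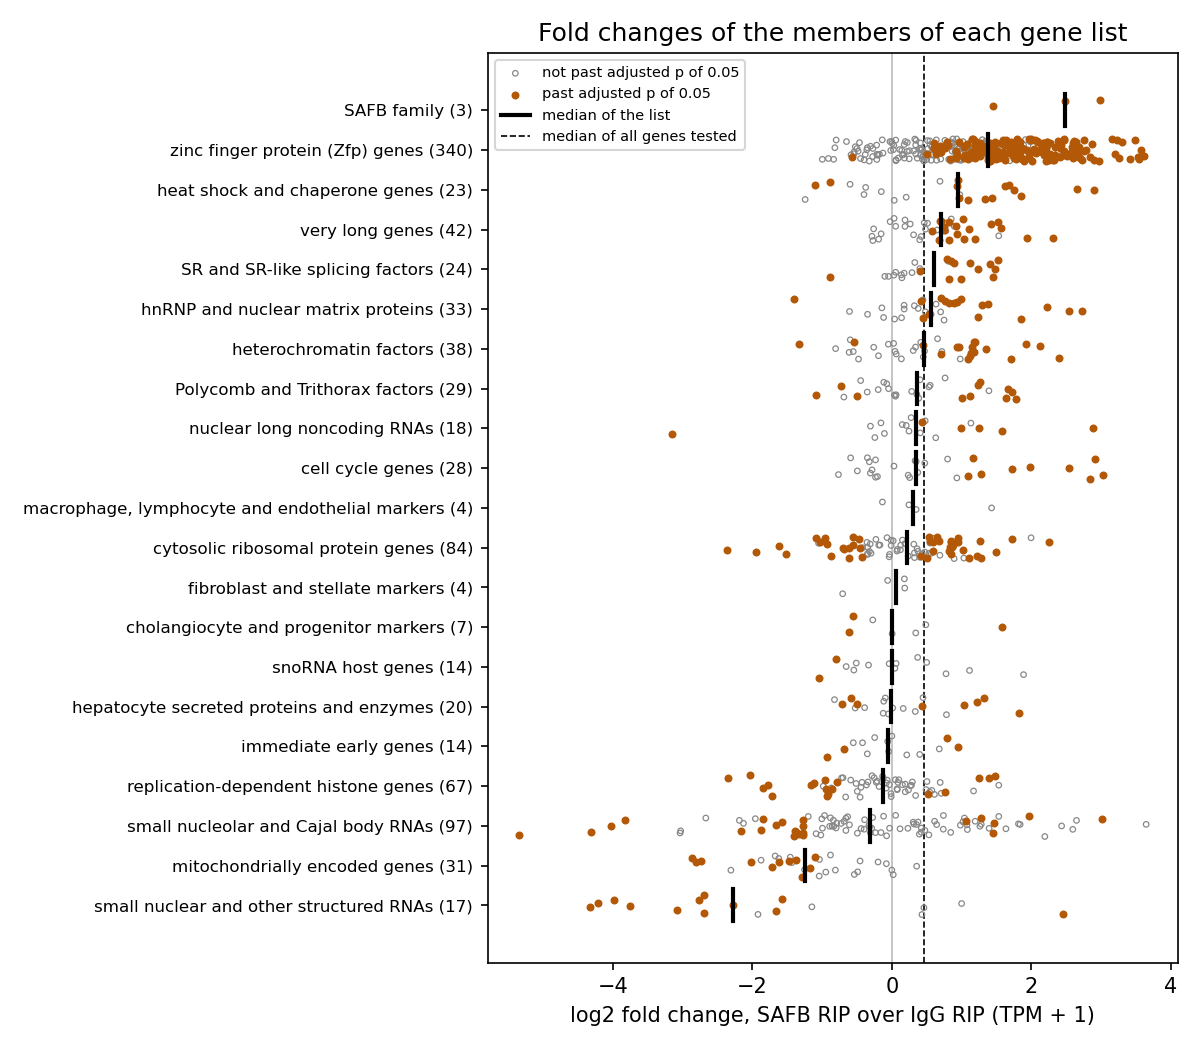
Log2 fold change of each tested member of the 21 gene lists (SAFB RIP over IgG RIP, on TPM + 1), with the number tested in brackets, filled points past an adjusted p of 0.05, the median of each list as a bar and the median of all genes, 0.46, as a dashed line. The highest median is that of the SAFB family, at 2.49, and the lowest that of the small nuclear and other structured RNAs, at -2.28.

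The genes with the largest fold changes upward were mostly short single-exon models inside other genes. Of 18 such genes taken by the naming rule, 12 were processed pseudogenes and 13 lay in an intron of a protein-coding gene on the same strand, so they are uncertain. Rpl21-ps12 (chromosome 6, 90844981 to 90845460, in an intron of Iqsec1) stood at 0.798 ± 1.13 TPM in the IgG RIP and 189 ± 7.94 TPM in the SAFB RIP, a log2 fold change of 6.88 ± 0.51. Hmgb1-rs16, in an intron of Dnajc13, stood at 6.07 ± 0.33. AC163354.2, Gm9670 and Gm44917 were listed at 0 in both IgG libraries and had means of 54.8, 96.0 and 95.7 TPM in the SAFB RIP. Gm13717 (6.74 ± 0.77), Ldhal6b (5.26 ± 0.41), Mir181b-2 (5.07 ± 0.96), Mir5119 (4.92 ± 0.63), BC002163 (4.83 ± 0.41), AC124577.2 (4.72 ± 0.51) and H2al1m (4.71 ± 0.62) rose as well. In the other direction, 4930448E22Rik was listed at 0 in both SAFB libraries and had 39.5 and 6.73 TPM in the IgG libraries, and Gm22133 stood at -0.98 ± 0.20. AY036118 fell from 115658 ± 38839.5 to 6821 ± 3152 TPM (-4.12 ± 0.51, or -2.65 after quantile normalization).

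No list passed with an estimated correlation, against 7 with the preset one. The former test has only 2 residual degrees of freedom, so its failure decides nothing. With the preset correlation the degrees of freedom come from the number of genes, so passing rests on fixing the correlation. Mitochondrially encoded genes had an estimate of -0.026, below the preset 0.01, and still did not pass. Estimates for very long genes (-0.016) and the SAFB family (-0.007) were below it too. Those of the remaining lists among the 7 were above it, at 0.025 to 0.129. The fold changes are on log2(TPM + 1) and understate low genes.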

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

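The rescaling of protein-coding genes alone and the removal of length and GC trends were chosen after the data had been seen. Of 94 genes followed, 58 kept direction and call under every alternative in which they were tested, 10 changed direction under at least 1, 23 lost a call and 11 gained one. Of 21 lists 10 kept both. Genes and lists missing from an alternative, such as small RNAs where these were left out, count as unchanged there. Genes higher and lower numbered 2736 and 2935 with median-centred libraries, 2758 and 2986 with quantile normalization, and 2600 and 2322 with protein-coding genes alone, against 4964 and 1382 as deposited. Median centring moves the genes of a library together, while quantile normalization moves them by rank. Requiring an absolute log2 fold change of at least 1 left 3969 higher and 601 lower as deposited, and 2155 and 1859 with median-centred libraries. Lists past the threshold numbered 3 with mitochondrial and small structured RNAs left out and 4 with protein-coding genes alone, where listed RNAs are missing, and 0 with an estimated correlation. Values on the other side of 0 after median centring were Firre -0.19, Exoc4 -0.27, C3 -0.13 and Fn1 -0.28, none of them called as deposited. After quantile normalization they were Rn7sk 0.63 and Exoc4 -0.12, with protein-coding genes alone Exoc4 -0.11 and Fn1 -0.12, with the length trend removed Gas5 0.0511, Fn1 -0.11 and Vim 0.0116, and with the GC trend removed Hist1h4n 0.00851, Exoc4 -0.10 and Krt19 0.0184. For lists, the direction relative to other genes changed where none passed. For cell cycle genes the medians there were 0.37 and 0.36 with pseudocounts of 0.1 and 0.5, 0.34 with no filter, -0.12 after median centring, 0.25 without the small RNAs and 0.22 without the GC trend. For macrophage, lymphocyte and endothelial markers they were 0.24 with no filter and 0.74 without the GC trend, for nuclear long noncoding RNAs -0.12 after median centring and 0.25 without the GC trend, and for Polycomb and Trithorax genes -0.10 after median centring and 0.19 without the length trend. Apart from the scalings and the missing genes, the cause was not tested. Leaving out 1 library at a time, with the lone library assumed to vary like the other group, gave 2605 to 10412 genes past the threshold, 2034 to 7781 higher and 571 to 2631 lower. The lowest of each came without SAFB RIP replicate 1 and the highest without IgG RIP replicate 2. The ranges were -0.14 to 0.0193 for Vim, -0.18 to 0.0948 for Gas5 and -0.28 to 0.00975 for Cd14. List medians ranged from 0.28 to 0.51 for nuclear long noncoding RNAs, 0.20 to 0.39 for Polycomb and Trithorax genes and -0.24 to 0.69 for the macrophage, lymphocyte and endothelial markers. With the replicate number as a block, 6061 genes passed, 4797 higher and 1264 lower, and 8 lists. Deviations of equally numbered libraries correlated at -0.02 across genes, so the numbers were not shown to pair the libraries. Read depth is unknown, which leaves open how far low values are limited by counting.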

Other observations

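The biotype groups, the multi-exon genes, Airn and the rescaling of protein-coding genes alone were chosen after the data had been seen, and the pseudogene tests were devised once pseudogenes were seen among the leading genes, before their own results were known. Of 503 lincRNAs tested, 219 rose and 12 fell, with a median log2 fold change of 1.27, and of 446 antisense genes 186 rose and 4 fell, with a median of 1.23, though the use of strand in counting is not known. Both groups stood above other genes (limma camera, Benjamini-Hochberg adjusted p = 0.000309 for each), but not with an estimated correlation (adjusted p = 0.263 with an estimated correlation). Genes can pass the filter through the SAFB libraries alone, and 711 of all genes called higher were listed at 0 in both IgG libraries. How far this raised these classes, or the processed pseudogenes below, was not tested. The median of all genes tested was itself 0.46. Of 17 mitochondrial tRNAs 0 rose and 3 fell, with a median of -1.04 (limma camera, Benjamini-Hochberg adjusted p = 7.51e-05; adjusted p = 0.263 with an estimated correlation). Of 508 miRNA genes 95 rose and 31 fell, with a median of 0.42, and the class did not stand apart (limma camera, Benjamini-Hochberg adjusted p = 0.0938). Airn, the imprinted noncoding RNA that silences Igf2r, rose from 115 ± 0.830 to 849.6 ± 32.4 TPM (SD, n = 2), a log2 fold change of 2.88 ± 0.09.

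Protein-coding genes with at least 2 exons and a mean of at least 10 TPM in both groups were ranked, which leaves out genes low in either group. Among them, the largest rises included Zfp3 (3.54 ± 0.16), Tmf1 (3.48 ± 0.15), Bod1l, a gene for a protein that protects replication forks (3.35 ± 0.12), and Fyco1, for an adaptor of autophagosome transport (3.09 ± 0.09). The largest falls included Spr, for sepiapterin reductase (-2.56 ± 0.18), Rpl18 (-2.37 ± 0.09) and Tspo, for a protein of the outer mitochondrial membrane (-1.90 ± 0.11). Genes called higher had a median GC content of 46.1% in their longest transcript, against 55.9% for genes called lower and 50.6% for the rest.

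With TPM as deposited, more genes were higher than lower in the SAFB RIP (78.2% of calls), but not with median-centred libraries (48.2%) or quantile normalization (48.0%). For lower depth of the IgG libraries, a limit of at most 60% of calls higher at a mean of at least 50 TPM had been set beforehand. Among 2454 such calls 68.2% were higher as deposited (± 1.84 points if genes were independent, which they are not). The scaling between libraries moves this share too, so the value cannot separate depth from scaling and decides nothing about depth. With protein-coding genes alone rescaled, 52.8% of calls were higher, but that rescaling centres these genes by itself (median log2 fold change 0.34 as deposited, 0.07 rescaled), so it decides nothing about the share of TPM taken by other RNAs in the IgG libraries, which stays open. A wide binding of SAFB to nuclear RNA is not excluded and was not tested, since TPM gives no amount of RNA per library.

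Protein-coding transcripts with more of the purine motif GAAGA stood higher in the SAFB RIP. The median was 2.86 per kb for genes called higher and 1.61 for genes called lower, and the rank correlation with log2 fold change across 11896 genes, which are not independent replicates, was 0.358. It was 0.362 given transcript length and 0.320 given GC content, so neither bias removed it, although GC content itself correlated at -0.503. Given both it was 0.323 (95% bootstrap interval 0.307 to 0.342), against -0.110 for the reverse complement CTTCT, among 29 relations computed. Binding of SAFB to purine-rich RNA may underlie this, but the purine percentage of the transcript correlated at 0.408, so the motif was not separated from purine content.

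Of 895 processed pseudogenes tested, 441 were higher in the SAFB RIP, and the class stood above other genes (limma camera, Benjamini-Hochberg adjusted p = 0.000136), but not with an estimated correlation (adjusted p = 0.263 with an estimated correlation). Those in an intron of a protein-coding gene on the same strand had a median of 2.31 (187 of 293 higher) and those outside other gene models 1.12 (171 of 422), a difference of 1.195 (95% bootstrap interval 0.831 to 1.497, permutation p = 0.0001, the smallest that 10000 permutations can give). That permutation was over pseudogenes of the same 4 libraries, which are not independent replicates. On the opposite strand of an intron the median was 1.13 (35 of 74 higher). Intronic RNA of the host gene may therefore be counted for them. Reads shared with the parent gene stay open as well, since over 63 ribosomal protein pseudogenes the median of pseudogene minus parent was 0.453 (95% bootstrap interval 0.0729 to 0.802), within the limit of 0.5 set beforehand, yet 30 lay over 0.5 above the parent and 12 over 0.5 below, so that median decides nothing (Rpl21-ps12 stood at 6.88 and Rpl21 at 1.10).

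The partial rank correlation of total intron length with log2 fold change, given transcript length and GC content, was 0.052 (95% bootstrap interval 0.031 to 0.071). The median absolute log2 difference between the IgG libraries was 1.92 times that between the SAFB libraries in genes with a mean of at least 100 TPM (95% bootstrap interval 1.81 to 2.05). AC157822.1, which overlaps the 7SL copy Rn7s2, had 0.953 and 16167 TPM in the IgG libraries, and Scarna10 0 and 1569 TPM. Cldn2, a claudin gene, had 309.8 and 0.203 TPM in the SAFB libraries, against 277 and 379 in the IgG libraries.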
